A study of Arabidopsis thaliana with 8 samples.

How the data were processed

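The series holds RNA sequencing of rosette leaves of Arabidopsis thaliana Col-0 in 4 groups of 2 libraries: control, copper deficiency, iron deficiency and both deficiencies. Per the labels, plants grew 12 d on soil and 10 d in hydroponics with 1 µM copper sulfate, and were then kept 10 d on the same medium, without copper sulfate and with 10 µM of the copper chelator bathocuproine disulfonate, without iron, or without both. Leaves were harvested 4 h after light onset and RNA was extracted with Trizol. The labels also give the plants' age as 20 d, which does not match the sum of these periods, and it is not resolved here. Libraries were unstranded, so that transcripts of opposite strands at 1 locus cannot be told apart. Whether the 2 libraries of a group came from separate cultures, and what the replicate numbers share across groups, is not given in the sources used here.

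The submitters' processing notes name Trimmomatic, TopHat2 2.1.1, Cufflinks and Cuffdiff. The deposited values are FPKM per gene and library from Cufflinks, written by the authors with a lower and upper bound, and no scaling between libraries is stated. The genome build and the annotation are not given in the sources used here. Each library listed 38093 gene entries with 38088 distinct identifiers, of which 5 stood at 2 loci. Identifiers were matched to the reference annotation (99.2% found, of these 99.9% with identical start and end once 1 was added to the start), from which symbols and gene types were taken. Coordinates are those of the deposited values, with 1 added to the start.

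Read totals are not given in the sources used here, so depth is known in relative terms only. It was read from the width of the deposited bounds under a Poisson model in 11993 genes, where the squared ratio of a value to its standard deviation gives the fragments it implies, with the deepest library set to 1: control 0.803 and 0.725, copper deficiency 0.755 and 0.927, iron deficiency 0.859 and 1, double deficiency 0.914 and 0.938. Genes at 1 FPKM or more numbered 16842 to 18396 per library. Nuclear messenger RNA made up 69.1 to 93.2% of the FPKM.

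Genes with at least 1 FPKM in at least 2 of the 8 libraries were tested (19170 genes). Log2(FPKM + 1) was fitted with limma 3.58.1 (lmFit, then eBayes with a trend in mean expression) in R 4.3.3, in 1 model of the 4 groups. Contrasts were each deficiency against control, the deficiencies against each other, and the interaction, which is the change in double deficiency less the sum of the 2 single changes. P-values were adjusted by the method of Benjamini and Hochberg, and genes with an adjusted p under 0.05 are called. Every p-value given for a gene is a limma adjusted p unless stated, errors of log2 changes are standard errors from limma, and errors of FPKM are standard deviations of 2 libraries. The median log2 change of all genes was 0.01 for copper, 0.27 for iron and 0.41 for double deficiency and 0.14 for the interaction, and list medians are given relative to it. A gene listed at 0 in a group is given by its library values, without a fold change.

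Gene lists (28 lists of 355 genes) covered copper and iron homeostasis, photosynthesis, reactive oxygen, hormones, other nutrients, the clock, senescence, flavonoids and markers of cell types that the sample could hold. They were tested with limma's camera at a preset correlation between genes of 0.01 and again with the correlation estimated from the residuals. The second form rests on the 4 residual degrees of freedom of the fit, so it had little power to call a list. Of these lists 27 had at least 3 tested members. The root list had 1 and was not tested. Members were also adjusted over their list alone. The tests, lists, alternatives and the rule for named genes were chosen before the data were examined. Named genes were the 5 largest rises and falls among called genes that moved alike in both libraries, the members with the largest change of each list described (2 to 4), and a fixed panel of 15 copper and iron genes. As many of the ranked genes were listed at 0 somewhere, the 5 largest rises and falls among called nuclear protein-coding genes with a locus of at least 300 bp and above 0 in all libraries were added after the data were seen, and the choice of lists to describe was widened after their results were seen.

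Comparisons that share the 2 controls were set against 50 simulations of unchanged groups. In each of these, the groups shared 2 control libraries simulated around the control means. Annotation terms of 20 to 500 genes in the reference notes (158 terms) were tested by Fisher's exact test, a test added after the data were seen. The background was 11994 tested nuclear coding genes with an annotation, genes listed at 0 included. For iron and double deficiency the sets were called genes that lay at least 1 on the log2 scale from the all-gene median. For the interaction and for double against iron deficiency no such distance was required. The procedure was tested on simulated data of the same size for copper deficiency against control: of 100 genes each with a log2 change of 1 and of 2 it called 62 and 84, and of 18970 unchanged genes 6. Of 1 changed and 20 unchanged lists it called 1 and 0. The simulated genes varied independently, and the changed ones were drawn from genes with a mean log2 value above 1. False calls among lists of correlated genes were therefore not measured, and estimated correlations reached 0.847 (photosystem I). Simulated values were normal around each gene's mean with its fitted spread, and none was listed at 0. The rates of calls therefore do not cover genes listed at 0 in a group. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 read the files and drew the figures. Alternatives were other pseudocounts (0.1 and 5), other filters, median-ratio and quantile scaling, other models of the spread, library weights, the compared groups alone, blocks by replicate number and by the letter in the titles, and each library left out in turn. Added after the data were seen were a test of genes above 0 in all libraries, scaling to the sum of nuclear protein-coding genes, and leaving out library copper 2 with library iron 1.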

Results

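In rosette leaves of plants kept for 10 d without copper and with a copper chelator, messenger RNA of the iron superoxide dismutase FSD1 stood at 723 ± 16.6 FPKM (mean ± SD, n = 2), against 328 ± 102 FPKM in controls (n = 2). The copper/zinc superoxide dismutases lay the other way: CSD2, the plastid enzyme, at 339 ± 23.7 against 721 ± 178 FPKM, and CSD1, the cytosolic enzyme, at 325 ± 33.7 against 480 ± 43.2 FPKM. Their copper chaperone CCS stood at 64.0 ± 9.97 against 116 ± 23.7 FPKM. Plants short of copper are known to exchange copper/zinc for iron superoxide dismutase through the regulator SPL7 and the microRNA miR398. The log2 differences from control were 1.17 ± 0.36 (SE) for FSD1 (limma adjusted p = 0.946), -1.07 ± 0.18 for CSD2 (0.301), -0.85 ± 0.17 for CCS (0.540) and -0.56 ± 0.13 for CSD1 (0.698), so none of these 4 was called among 19170 genes. Adjusted over the list of copper microRNA targets and copper proteins alone, CSD2, CCS and CSD1 fell. In iron deficiency and in the double deficiency FSD1 was close to absent, at 1.14 ± 0.966 and 0.611 ± 0.401 FPKM, with CSD2 at 729 ± 85.9 and 725 ± 18.7 FPKM. FSD1 lies on chromosome 4 from 12884300 to 12887011, and CSD2 on chromosome 2 from 12014412 to 12016569.

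**Figure D1:**
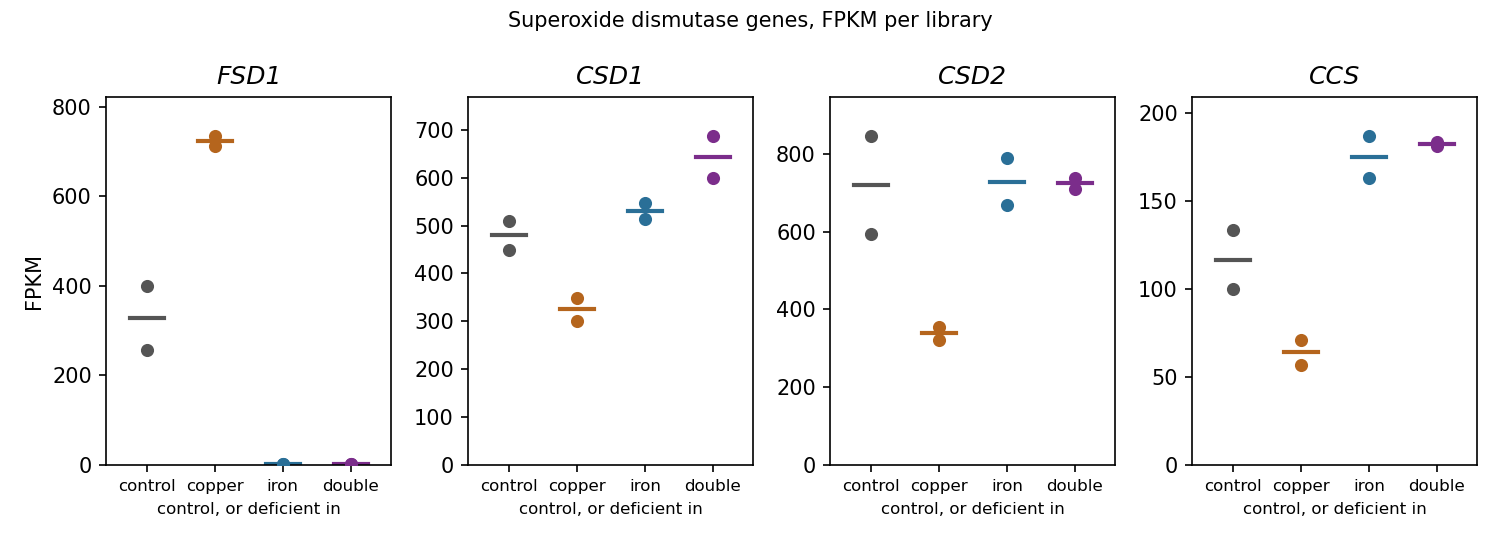
Messenger RNA of FSD1, CSD1, CSD2 and CCS in rosette leaves of the 4 groups. Dots are single libraries, bars are means (n = 2 per group), in FPKM on linear axes that start at 0. FSD1 was not called for copper deficiency and fell in iron and in double deficiency. The rises of CCS in iron and double deficiency and of CSD1 in double deficiency were called on the deposited scale and were lost under median-ratio scaling, where CSD1 turned to a log2 change of -0.03.

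Of the other genes that copper-starved leaves are known to regulate, the copper importer COPT2 stood at 5.67 ± 0.782 against 3.51 ± 1.46 FPKM in controls (log2 0.60 ± 0.29, adjusted p = 0.946). The copper chaperone CCH stood at 239 ± 50.6 against 185 ± 4.03 FPKM (0.35 ± 0.14, 0.946) and the metal transporter YSL2 at 2.56 ± 0.00501 against 1.116 ± 0.861 FPKM (0.81 ± 0.32, 0.946). The copper-response list held 18 genes, of which only 8 could be tested, so most of the list is not covered here. As a list, 6 of 8 tested copper-response genes lay above control, with a median of 0.24 above the all-gene median of 0.01 (camera adjusted p = 0.0780, and adjusted p = 0.661 with an estimated correlation). The list of copper microRNA targets and copper proteins lay below control in 8 of 10 members, with a median of -0.30 relative to all genes and 0 members called (adjusted p = 0.00139, and adjusted p = 0.416 with an estimated correlation). The laccase LAC3 of this list stood at 0.134 ± 0.0670 against 0.713 ± 0.890 FPKM (-0.49 ± 0.45, 0.948).

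By median, salicylate defence genes were the list that moved furthest without copper, while by mean the dividing-cell markers did (0.71 against -0.70). All 16 tested salicylate members lay below control, with a median of -0.65 relative to all genes and 0 called (adjusted p = 5.71e-09, and adjusted p = 0.661 with an estimated correlation). This list also lay lower in iron (-0.55) and double deficiency (-0.64). All comparisons share the 2 controls, so high values in these controls cannot be told apart from an effect of copper deficiency. The pathogenesis marker PR1 stood at 19.3 ± 0.797 against 45.3 ± 12.8 FPKM (-1.16 ± 0.41, 0.946), the camalexin enzyme PAD3 at 1.91 ± 0.930 against 5.04 ± 2.13 FPKM (-1.04 ± 0.32, 0.946), and WRKY38 at 1.34 ± 1.46 against 3.65 ± 0.759 FPKM (-1.14 ± 0.45, 0.946). The salicylate exporter EDS5 was listed at 0 in 5 of 8 libraries, with 5.52 FPKM in 1 control. Chlorophyll synthesis genes lay above control in 18 of 20 members (median 0.11 relative to all genes, 0 called, adjusted p = 0.0116, and adjusted p = 0.951 with an estimated correlation), with CHLI2 at 73.2 ± 0.429 against 58.1 ± 7.15 FPKM and HEME1 at 134 ± 11.3 against 108 ± 2.78 FPKM. All 5 guard cell markers lay above control (median 0.31, 0 called, adjusted p = 0.0151, and adjusted p = 0.661 with an estimated correlation), among them MYB60 at 8.39 ± 1.98 against 5.95 ± 0.879 FPKM and the myrosinase TGG1 at 2070 ± 63.7 against 1660 ± 96.5 FPKM. The chlorophyll list lost its call without control 1 (adjusted p = 0.295) or copper 2 (0.0952), and the guard cell list without control 2 (0.188) or copper 2 (0.112), libraries being named by group and replicate. Chloroplast-encoded transcripts made up 0.278% of the FPKM in library copper 2 and 5.83 to 11.2% in the other 7 libraries. The other 22 lists gave adjusted p from 0.0780 to 0.971.

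The 35 genes that were called for copper deficiency (21 rose and 14 fell; 21 and 15 under median-ratio scaling) were of another kind. Each had a group with both libraries listed at 0, and 13 of them were not nuclear protein-coding genes with a locus of at least 300 bp. The small open reading frame AT1G55673 was listed at 0 in both controls and at 1347 and 2176 FPKM without copper, and the transfer RNA genes AT1G28800 and AT1G28860 at 0 in the controls and at 949 and 470, and 463 and 470 FPKM. AT3G28918 (564 and 754 FPKM) and the pseudogene AT3G30812 (47.7 and 217 FPKM) were likewise listed at 0 in the controls. In the other direction the microRNA precursor MIR418 stood at 694 and 943 FPKM in the controls, the small nucleolar RNA AT4G39361 at 351 and 485, the spliceosomal RNA U4.8 at 179 and 169, AT5G01145 at 148 and 150, and AT4G06460 at 20.8 and 51.9, and all 5 were listed at 0 in both copper-deficient libraries. No gene was called among nuclear protein-coding genes above 0 in all 8 libraries (limma on these 16801 genes; 895 passed an unadjusted p of 0.05, where 840 would by chance). Over the 19170 genes, 937 passed an unadjusted p of 0.05, where 958.5 would by chance. Without copper 1, 86 genes were called, without control 1, 56, at 5 FPKM in 2 libraries 23, and scaled to nuclear coding transcripts 22. AT3G30812 lost its call without either control, iron or double library (adjusted p from 0.0525 to 0.109) and AT4G06460 without copper 2 (0.0525).

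Iron deficiency changed the leaf transcriptome widely. The regulators BHLH39, BHLH100 and IMA2, which plants are known to switch on when iron is short, rose from 0.163 ± 0.0167, 0.546 ± 0.591 and 1.14 ± 0.135 FPKM in controls to 360 ± 20.6, 634 ± 4.75 and 821 ± 30.6 FPKM (n = 2 per group). Their log2 changes were 8.28 ± 0.12 (adjusted p = 7.62e-07), 8.74 ± 0.44 (9.37e-05) and 8.59 ± 0.31 (2.47e-05). All 15 tested members of the leaf iron response rose, with a median of 3.90 relative to all genes (adjusted p = 1.02e-10, and adjusted p = 0.350 with an estimated correlation). They included the peptide IMA1 (7.48 ± 0.68, 0.000904), the reductase FRO3 (4.66 ± 0.30, 0.000249) and the phloem iron transporter OPT3 (3.02 ± 0.23, 0.000453). BHLH38 stood at 0 and 0.914 FPKM in the controls and at 626 and 678 FPKM without iron, and BHLH101 was listed at 0 in all 8 libraries. Further large rises, by rank, were AT2G14247 (7.71 ± 0.35, 6.15e-05) and the P-loop hydrolase AT2G18193 (7.36 ± 0.18, 5.60e-06). BHLH39 and BHLH38 are close paralogs that lie side by side, so that their shares of the reads are less sure than their sum.

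Genes of iron storage and sufficiency fell in 7 of 11 tested members and rose in none, with a median of -1.96 relative to all genes (adjusted p = 8.83e-08, and adjusted p = 0.350 with an estimated correlation). The iron-sulfur protein NEET fell from 225 ± 20.1 to 0.366 ± 0.155 FPKM (-7.37 ± 0.38, 0.000105), the ferritin FER1 from 75.9 ± 23.4 to 7.11 ± 1.06 FPKM (-3.22 ± 0.25, 0.000502) and the nicotianamine synthase NAS3 from 7.12 ± 0.0890 to 0.377 ± 0.192 FPKM (-2.57 ± 0.29, 0.00186). The ferritin FER4 stood at 17.8 and 13.7 FPKM in the controls and was listed at 0 in both iron-deficient libraries. FSD1, which holds iron, fell by 7.30 on the log2 scale (± 0.36, 9.01e-05). By rank the next largest falls were ENH1, a rubredoxin-like plastid protein (-5.46 ± 0.27, 8.73e-05), HEMA1 (-4.52 ± 0.23, 0.000100) and MEE3 (-4.52 ± 0.18, 3.89e-05). In the root-type iron uptake list, FRO2 rose from 0.640 ± 0.0202 to 15.0 ± 0.317 FPKM (3.28 ± 0.17, 0.000113) and IRT1 to 9.21 ± 0.960 FPKM (3.03 ± 0.24, 0.000521). The other 5 tested members were not called, among them F6'H1 (1.58 ± 0.83, 0.188) and BTSL2 (0.34 ± 0.21, 0.2502), and the list gave an adjusted p of 0.137.

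Nuclear photosynthesis genes fell together without iron. In photosystem II and its antenna 21 of 22 members fell and PSBS was not called (median -1.64 relative to all genes, adjusted p = 6.30e-21, and adjusted p = 0.350 with an estimated correlation). In photosystem I all 16 fell (median -1.64, adjusted p = 5.33e-19, and adjusted p = 0.350 with an estimated correlation). PSAN, a subunit on the lumen side, fell from 3619 ± 221 to 229 ± 66.4 FPKM (-4.01 ± 0.21, 0.000105), ahead of PSAF (-2.70 ± 0.19, 0.000348), PSAD2 (-2.61 ± 0.17, 0.000248) and PSAD1 (-2.08 ± 0.15, 0.000375). Of the antenna, LHCB2.4 fell by 2.42 (± 0.16, 0.000284), LHCB6 by 2.19 (± 0.19, 0.000822) and LHCB5 by 1.99 (± 0.17, 0.000793) on the log2 scale, and PSBQ2 of the oxygen-evolving complex by 2.29 (± 0.17, 0.000402). Chlorophyll synthesis fell in 14 of 20 members, 17 when adjusted over the list alone (median -0.79, adjusted p = 3.20e-14, and adjusted p = 0.360 with an estimated correlation). HEMA1, the entry enzyme, fell from 289 ± 8.40 to 11.9 ± 3.90 FPKM, with PORB (-2.26 ± 0.15, 0.000300), PORA (-1.46 ± 0.22, 0.00489) and DVR (-1.28 ± 0.12, 0.00116) behind it. In the Calvin-Benson cycle 9 of 18 fell, 13 over the list alone (median -0.80, adjusted p = 1.02e-10, and adjusted p = 0.360 with an estimated correlation), led by RPE (-1.46 ± 0.12, 0.000635), RBCS3B (-1.01 ± 0.17, 0.00695), RBCS2B (-0.83 ± 0.17, 0.0130) and SBPASE (-0.76 ± 0.16, 0.0151). Direction held under each scaling, while the numbers that fell in these 4 lists came to 21, 16, 20 and 16 under median-ratio and 14, 12, 16 and 5 under quantile scaling, and 1 gene of photosystem II rose when libraries were scaled to nuclear coding transcripts. Antenna and RBCS genes are near-identical paralogs, so single members are less sure than the family. RBCS3B lost its call without control 2 (adjusted p = 0.0557), RBCS2B without control 1 or 2 (0.0504 and 0.0809) and SBPASE without control 2 or iron 1 (0.0838 and 0.0641). Ribosomal RNA took 5.94 and 1.66% of the FPKM in the iron-deficient and 2.62 and 2.68% in the doubly deficient libraries, against 0.358 and 0.661% in the controls and 0.474 and 0.0760% without copper. Mitochondrial transcripts took 0.0699 and 0.553% and 0.305 and 0.598%, against 0.0137 and 0.0147% in the controls and 0.0114 and 0.00324% without copper, so that RNA composition differed by group. In the same comparison 3 of 4 dividing-cell markers and 5 of 10 flowering markers rose (2 and 4 under median-ratio scaling), with neither list called (adjusted p = 0.103 and 0.241), and no shares of cell types were estimated. In library iron 1 the chloroplast gene psbA stood at 1181 FPKM (13.3 to 44.9 in the others).

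Plastid iron-sulfur genes divided. Of 16 tested, 6 fell and 3 rose (median -0.47 relative to all genes, adjusted p = 7.36e-05, and adjusted p = 0.360 with an estimated correlation), and on the raw scale the median turned from -0.20 to 0.06 when libraries were scaled to nuclear coding transcripts. The leaf ferredoxin FD2 fell from 2839 ± 157 to 262 ± 59.8 FPKM (-3.45 ± 0.22, 0.000231), SUFB of the assembly scaffold by 2.65 on the log2 scale (± 0.17, 0.000260), the sulfite reductase SIR by 1.23 (± 0.18, 0.00430) and PETC of the cytochrome complex by 1.15 (± 0.14, 0.00277). Among reactive oxygen genes 5 rose and 5 fell of 14 (adjusted p = 0.230): the peroxidase SAPX fell by 3.53 (± 0.10, 1.25e-05) and the catalase CAT3 by 3.27 (± 0.21, 0.000224), and the zinc finger ZAT12 rose by 2.94 (± 0.13, 5.89e-05). OXI1, listed at 0 in 1 copper-deficient library, rose from 0.163 and 0.204 FPKM in the controls to 8.15 and 10.8 FPKM. The median of this list was 0.20, the mean -0.17 and the test pointed down, and the median turned to -0.09 under median-ratio and -0.02 under quantile scaling.

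Single copper genes changed without iron, while none of the 3 copper lists was called. The copper pump HMA5 rose from 0.419 ± 0.126 to 8.14 ± 1.17 FPKM (2.68 ± 0.18, 0.000261), RAN1 by 0.86 (± 0.10, 0.00214) and the copper regulator SPL7 from 5.72 ± 0.427 to 11.8 ± 1.04 FPKM (0.93 ± 0.15, 0.00580). The plastocyanins PETE2 and PETE1 fell by 1.498 (± 0.17, 0.00186) and 0.44 (± 0.10, 0.0212) on the log2 scale. The delivery list held 2 rises and 2 falls among 8 (adjusted p = 0.483) and the copper-response list 2 rises and 1 fall, of FSD1, among 8 (adjusted p = 0.2501). COPT2 stood 0.85 ± 0.29 above control (0.0674), YSL2 -0.71 ± 0.32 (0.141) and CCH -0.18 ± 0.14 (0.363). Of the copper microRNA targets CCS rose by 0.60 (± 0.17, 0.0387; 0 called over the list alone), against 0.03 ± 0.18 for CSD2 (0.914) and 0.15 ± 0.13 for CSD1 (0.406). That list of 10 gave an adjusted p of 0.366, and its raw median, 0.08, turned to -0.21 under median-ratio and -0.09 under quantile scaling. The rise of CCS was lost under both and without control 1, either iron or either double library (adjusted p from 0.0661 to 0.165), and the fall of PETE1 without control 1, control 2 or iron 1 (0.0876, 0.0967 and 0.0594).

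Defence and abscisate genes lay lower and clock genes higher without iron. PR1 fell from 45.3 ± 12.8 to 2.101 ± 0.242 FPKM (-3.88 ± 0.41, 0.00161) and the glucanase PR2 by 1.24 (± 0.18, 0.00407) on the log2 scale, with PAD3 at -1.005 ± 0.32 (0.0550) and WRKY38 at -0.80 ± 0.45 (0.219). Of 16 salicylate genes these 2 fell and 1, ICS1, rose, the last not under median-ratio or quantile scaling (median -0.55 relative to all genes, adjusted p = 0.00141, and adjusted p = 0.502 with an estimated correlation). In the double deficiency 3 fell and 1 rose, 2 and 1 over the list alone (median -0.64, adjusted p = 2.87e-05, and adjusted p = 0.364 with an estimated correlation), with PR1 at -3.01 ± 0.41 (0.00228), PR2 at -1.12 ± 0.18 (0.00379) and NIMIN1 at -0.88 ± 0.29 (0.0463). Of 11 abscisate, drought and cold genes 4 fell without iron (median -0.76, adjusted p = 0.000124, and adjusted p = 0.350 with an estimated correlation), among them NCED3, the key enzyme of abscisate synthesis (-0.88 ± 0.23, 0.0264), and KIN2 (-0.79 ± 0.12, 0.00482), with KIN1 at -1.10 ± 0.55 (0.172) and RD29B at -0.65 ± 0.30 (0.142). Without both metals 4 fell, 5 over the list alone, and CBF2 rose (1.05 ± 0.25, 0.0165), the rise not under median-ratio or quantile scaling (median -0.84, adjusted p = 3.43e-05, and adjusted p = 0.243 with an estimated correlation). RD29A fell there by 1.57 (± 0.24, 0.00307), NCED3 by 1.19 (± 0.23, 0.00703) and KIN2 by 0.71 (± 0.12, 0.00468). Of 12 clock genes 7 rose without iron and 0 fell (median 0.37, adjusted p = 0.0203, and adjusted p = 0.485 with an estimated correlation), 4 under median-ratio scaling. The morning genes LHY, CCA1 and RVE8 rose by 2.49 (± 0.10, 4.52e-05), 1.53 (± 0.14, 0.000843) and 1.54 (± 0.13, 0.000642), and PRR5 by 1.23 (± 0.23, 0.00957). All libraries were harvested 4 h after light onset. The clock list lost its call without control 1 (adjusted p = 0.0501), PRR5 without iron 2 (0.0577) and NCED3 in iron deficiency without control 1, control 2 or iron 1 (0.0998, 0.0811 and 0.0908). In the double deficiency CBF2 lost its call without control 2 or either double library (0.0527 to 0.0813) and NIMIN1 without any of the control, iron and double libraries (0.0654 to 0.165).

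Over all genes, 6532 were called for iron deficiency, 5218 up and 1314 down, and 2019 of them by at least 1 on the log2 scale. The median gene stood 0.27 above control. Under median-ratio scaling, which sets that median near 0, 2760 rose and 2838 fell, and scaled to nuclear coding transcripts 10270 genes were called. The largest changes by rank included short transcripts listed at 0 elsewhere: AT2G05765 at 5298 and 4702 FPKM and the chloroplast gene ATCG00290 at 3049 and 5436 FPKM were listed at 0 in all 6 other libraries. How many fragments lie behind such values was examined for the copper calls alone, as given below. It is not known for the short genes named here and in the later comparisons. AT3G50825 (7228 and 2138 FPKM), AT3G08165 (2409 and 4277) and AT2G21360 (1522 and 3391) were listed at 0 in both controls, whereas MIR418, AT4G39361 and U4.8 were listed at 0 in both iron-deficient libraries. Of these AT3G08165 lost its call without any of the control, copper and iron libraries (adjusted p from 0.0586 to 0.153) and AT2G21360 without either control or iron library (0.0601 to 0.0878). Without control 2, 3376 genes were called, and without iron 2, 3463. With 2 samples per group and no statement that they came from separate cultures, these p-values measure the spread between these samples alone, which may be technical.

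**Figure D2:**
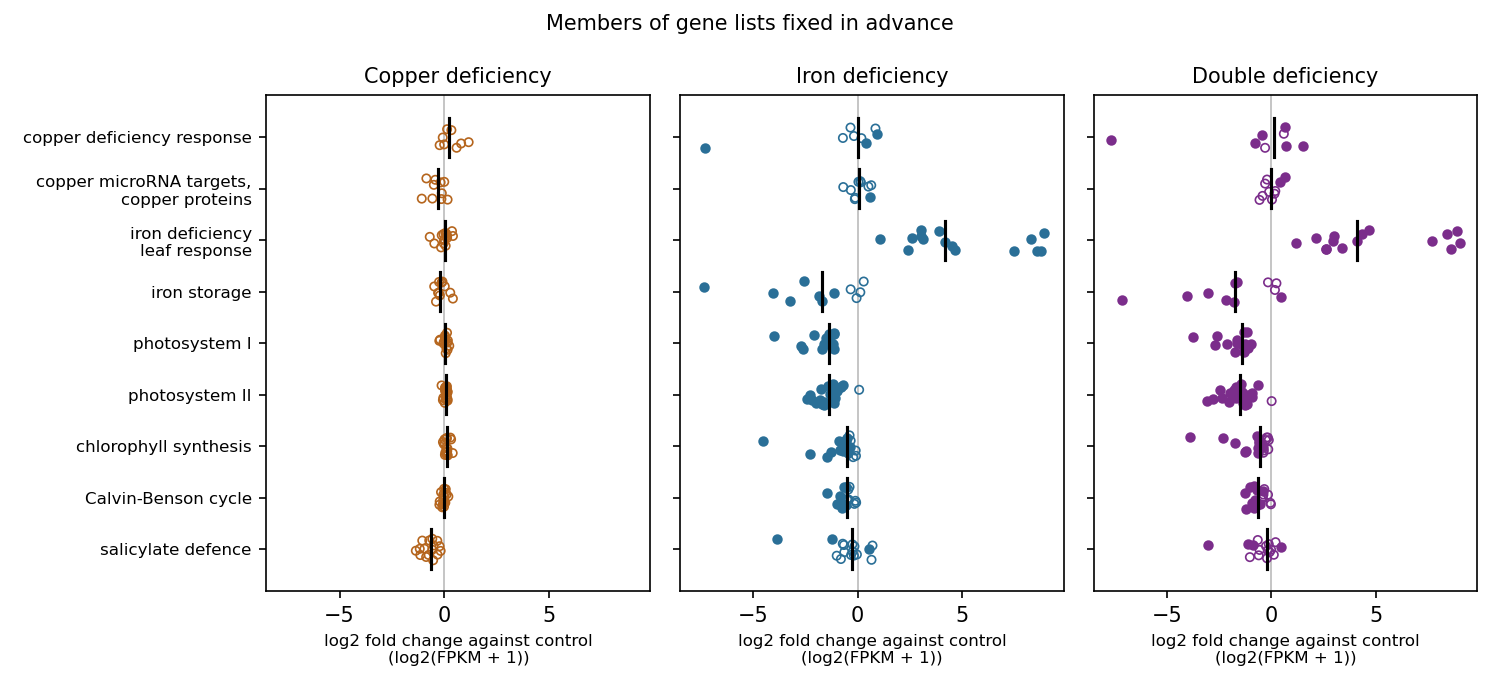
Log2 change against control of the tested members of 9 gene lists in copper, iron and double deficiency. Each dot is a gene, filled where its adjusted p was under 0.05 and open where not, and the black bar is the list median. Values are on the deposited scale, on which the median of all genes lies at 0.01, 0.27 and 0.41 in the 3 panels. Medians near 0 change sign with the scaling: that of the copper microRNA targets in iron deficiency turned to -0.21, and that of the copper-response list in double deficiency to -0.17, under median-ratio scaling.

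Leaves deprived of both metals showed the iron response again. BHLH39 stood at 393 ± 12.3 FPKM (n = 2; log2 change from control 8.41 ± 0.12, adjusted p = 1.20e-06), IMA2 at 1005 ± 53.6 FPKM (8.88 ± 0.31, 1.87e-05), BHLH100 at 569 ± 21.7 FPKM (8.58 ± 0.44, 8.30e-05), FRO3 at 248 ± 2.32 FPKM (4.66 ± 0.30, 0.000189) and OPT3 at 424 ± 18.7 FPKM (2.59 ± 0.23, 0.000532). All 15 tested members of the leaf response rose (median 3.70 relative to an all-gene median of 0.41, adjusted p = 1.95e-08, and adjusted p = 0.243 with an estimated correlation). AT2G14247 (7.91 ± 0.35) and AT2G18193 (7.88 ± 0.18) were again among the largest rises, and BHLH38 stood at 703 and 730 FPKM. Of the storage genes 7 fell and 1, FRO7, rose among 11 (median -2.14, adjusted p = 1.21e-08, and adjusted p = 0.243 with an estimated correlation), and the rise of FRO7 was lost under median-ratio and quantile scaling. NEET fell by 7.13 (± 0.38, 0.000100), and FER1 by 3.03 (± 0.25, 0.000439) on the log2 scale, NAS3 fell too (-2.17 ± 0.29, 0.00199), and FER4 was listed at 0 in both libraries. FSD1 fell by 7.66 (± 0.36, 6.13e-05), and ENH1 by 4.79 (± 0.27, 0.000118). AT3G55240 (-4.0998 ± 0.17, 3.59e-05) and the copper amine oxidase family gene AT3G43670 (-4.04 ± 0.15, 2.49e-05) fell as well. In the uptake list FRO2 (2.71 ± 0.17, 0.000181) and IRT1 (2.15 ± 0.24, 0.00110) rose among 7 (adjusted p = 0.524), with the regulator FIT at -0.41 ± 0.20 (0.151) and F6'H1 at -0.33 ± 0.83 (0.769). The median of that list was 0.02 and its mean 0.59, while the test pointed down, and the median turned to -0.40 under median-ratio scaling.

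Photosystem II fell in 21 of 22 members in the double deficiency (median -1.93 relative to all genes, adjusted p = 9.52e-27, and adjusted p = 0.243 with an estimated correlation) and photosystem I in all 16 (median -1.81, adjusted p = 1.90e-22, and adjusted p = 0.243 with an estimated correlation). LHCB2.4 fell by 3.06 (± 0.16, 9.75e-05), LHCB4.3 by 2.77 (± 0.23, 0.000448), PSBQ2 by 2.45 (± 0.17, 0.000232), LHCB6 by 2.38 (± 0.19, 0.000414) and PSAN by 3.74 (± 0.21, 0.000113) on the log2 scale. PSAF, PSAD2 and PSAD1 stood at -2.67, -2.58 and -2.14. Chlorophyll synthesis fell in 13 of 20 members, 15 over the list alone (median -0.93, adjusted p = 4.63e-17, and adjusted p = 0.243 with an estimated correlation), with HEMA1 at -3.89 ± 0.23, PORB at -2.32 ± 0.15, PORA at -1.75 ± 0.22 and CHLH at -1.26 ± 0.12. The Calvin-Benson cycle fell in 11 of 18 members, also 11 over the list alone (median -1.03, adjusted p = 9.48e-14, and adjusted p = 0.293 with an estimated correlation), with RPE at -1.24 ± 0.12, RBCS3B at -1.20 ± 0.17, PGK1 at -1.02 ± 0.12 and FBA2 at -0.93 ± 0.13. Of 16 plastid iron-sulfur genes 7 fell, 8 over the list alone, and 2 rose (median -0.68, adjusted p = 5.68e-07, and adjusted p = 0.243 with an estimated correlation). FD2 fell by 2.87 (± 0.22, 0.000351), SUFB by 2.25 (± 0.17, 0.000361), the nitrite reductase NIR1 by 1.38 (± 0.15, 0.00114) and SIR by 1.31 (± 0.18, 0.00221) on the log2 scale. Under quantile scaling 16 of the photosystem II genes fell and 1 rose, and 10 of photosystem I fell. Of the dividing-cell markers 3 of 4 and of the flowering markers 7 of 10 rose in this comparison (2 and 6 under median-ratio scaling), with neither list called (adjusted p = 0.146 and 0.0664).

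Copper genes in the double deficiency included COPT2, which rose from 3.51 ± 1.46 to 11.6 ± 1.63 FPKM (1.51 ± 0.29, 0.00769), and SPL7 (0.69 ± 0.15, 0.0116), while CCH fell by 0.43 (± 0.14, 0.0483) and FRO4 by 0.76 (± 0.23, 0.0365) on the log2 scale. The median of all genes stood at 0.41 in this comparison, so much of the rise of SPL7 lay within the general shift. The copper-response list held 3 rises and 3 falls among 8 (4 and 3 over the list alone, adjusted p = 0.126), with a median of 0.15, a mean of -0.72 and a test that pointed down. CCS rose by 0.66 (± 0.17, 0.0219) and CSD1 by 0.42 (± 0.13, 0.0354), 0 members were called over that list alone (adjusted p = 0.107), and CSD2 stood at 0.03 ± 0.18 (0.912). Both rises were lost under median-ratio scaling, where CSD1 turned to -0.03. CCS also lost its call without control 1 or either double library (adjusted p from 0.0793 to 0.0922), CSD1 without any control or double library (0.0602 to 0.186), CCH without any control, iron or double library (0.0691 to 0.155). FRO4 lost its call without any library but double 2 (0.0519 to 0.148) and SPL7 without control 2 or double 1 (0.0598 and 0.0722). The copper delivery list held 2 rises and 2 falls among 8 (adjusted p = 0.276). Among reactive oxygen genes 8 rose and 5 fell of 14 (adjusted p = 0.277; 4 and 5 under median-ratio scaling, with the raw median turning from 0.41 to -0.04). ZAT12 rose by 4.48 (± 0.13, 1.00e-05), and SAPX and CAT3 fell by 3.18 (± 0.10, 1.54e-05) and 3.19 (± 0.21, 0.000189). OXI1 stood at 15.2 and 17.38 FPKM.

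In all, 8654 genes were called for the double deficiency, 7506 up and 1148 down, and 3112 by at least 1 on the log2 scale. Under median-ratio scaling 3123 rose and 2969 fell. Among the changes ranked largest, AT3G50825 (2925 and 5031 FPKM), AT1G31258 (1036 and 657), AT1G55673 (720 and 703) and the spliceosomal RNA U5.6 (664 and 799) were listed at 0 in both controls, and MIR418, U4.8 and AT5G01145 were listed at 0 in both doubly deficient libraries. AT1G31258 lost its call without any control, iron or double library (adjusted p from 0.0533 to 0.114). Without double 1 or 2, 5174 and 5650 genes were called, and without control 2, 5630. Against copper deficiency alone 8779 genes were called for the double deficiency (7552 up and 1227 down; 3247 and 3126 under median-ratio scaling; 5235 and 5715 without double 1 or 2). Iron against copper deficiency gave 6703 genes (5252 up and 1451 down; 2816 and 2962 under median-ratio scaling; 10340 scaled to nuclear coding transcripts; 3612 without iron 2 and 3638 without copper 2 and iron 1).

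The iron and double deficiency changes followed each other gene by gene (r = 0.755, and 0.894 over nuclear coding genes above 0 in all libraries). Both were measured against the same 2 controls, so part of this may come from the shared controls: simulated unchanged groups gave a mean r of 0.495. The covariance was 0.695 against 0.123 in the simulations. Of the genes called in both comparisons 4660 rose in both, where independent calls (n1 × n2/N) would give 2043, and 872 fell in both, where they would give 78.7. In total 5542 genes were called in both. Simulated unchanged groups shared 0.04 calls, a reference near 0 that holds no effects and does not measure agreement. Copper and iron deficiency gave r = 0.289 (0.495 simulated), and 0.115 over nuclear coding genes above 0 in all libraries (0.173 when scaled to nuclear coding transcripts, 0.457 without control 1). The covariance was 0.169 against 0.124. As r falls where 1 comparison holds larger changes than the other, an r under the simulated 0.495 does not measure how much was shared. Copper and iron deficiency shared 7 rises (5.72 by independent calls) and 7 falls (0.960), 17 calls in all (0.06 simulated), each of a gene with a group listed at 0. These calls are no evidence of a shared response. Copper and double deficiency gave r = 0.261 (0.502 simulated; 0.0981 over nuclear coding genes above 0 in all libraries), a covariance of 0.156 (0.126 simulated), 7 shared rises (8.22 by independent calls) and 7 shared falls (0.838).

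**Figure D3:**
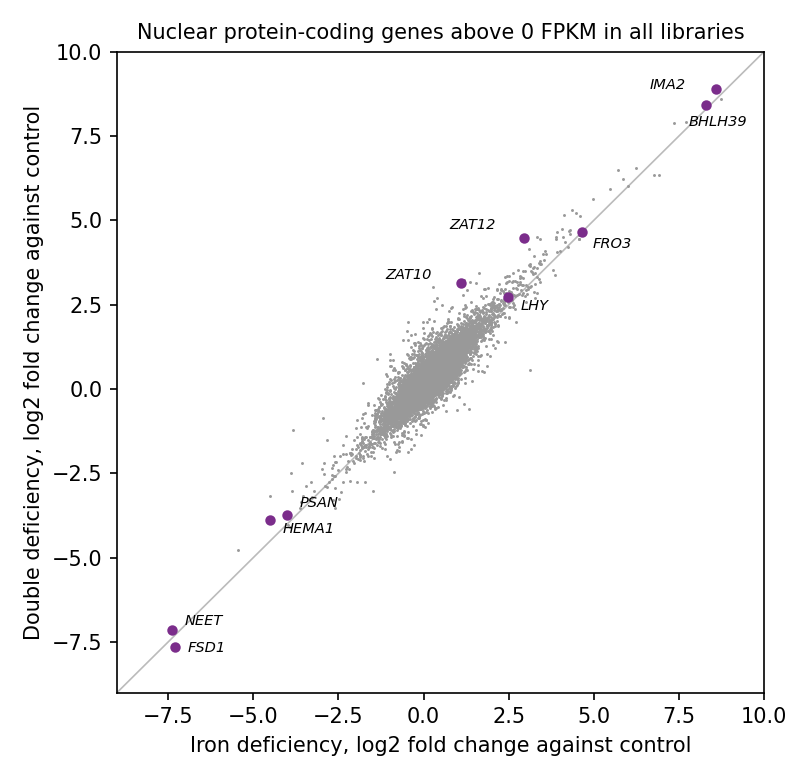
Log2 change of each gene in double deficiency against its change in iron deficiency, both against the same controls. Shown are 16801 nuclear protein-coding genes with a locus of at least 300 bp and a value above 0 in all 8 libraries, on the deposited scale. The line marks equal changes. Named genes keep their direction under each scaling.

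Where the effect of both deficiencies departed from the sum of the single ones, the zinc fingers ZAT12 and ZAT10, known to respond to oxidative and other stress, stood out. ZAT12 stood at 2.56 ± 0.232 FPKM in controls, 1.92 ± 0.264 without copper, 26.4 ± 2.88 without iron and 78.3 ± 4.17 without both (n = 2 each; interaction 1.82 ± 0.19 on the log2 scale, limma adjusted p = 0.0148). ZAT10 stood at 4.06 ± 0.498, 4.04 ± 0.670, 9.78 ± 1.89 and 43.3 ± 2.73 FPKM (2.06 ± 0.24, 0.0280). The zinc transporter ZIP4 went the other way, at 5.01 ± 0.215, 6.92 ± 0.982, 10.9 ± 0.163 and 2.90 ± 0.365 FPKM (-2.01 ± 0.20, 0.0148), as did the phloem sucrose carrier SUC2 at 67.7 ± 5.72, 75.3 ± 1.83, 70.5 ± 7.04 and 35.5 ± 1.48 FPKM (-1.12 ± 0.15, 0.0429). Among genes above 0 in all libraries the largest positive interactions were those of the blue copper-binding protein BCB (37.7 ± 7.68, 13.1 ± 6.06, 67.1 ± 6.79 and 204 ± 6.50 FPKM; 3.11 ± 0.42, 0.0438), AT1G36622 (2.61 ± 0.28, 0.0200), AT2G25735 (2.59 ± 0.35, 0.0467), the lipid-transfer family gene AT3G22600 (2.53 ± 0.27, 0.0198) and the glutaredoxin AT3G21460 (19.0 ± 0.870, 21.3 ± 3.06, 0.404 ± 0.145 and 7.69 ± 0.141 FPKM; 2.48 ± 0.21, 0.00544). The RING gene AT4G13100 was the third called fall of this kind (-1.13 ± 0.13, 0.0272). Each of these 10 calls was lost without some library, with its sign kept in each case: ZAT12 without control 1, iron 1 or either double library (adjusted p from 0.0534 to 0.135), and AT3G21460 without either double library (0.0551 and 0.0600). ZAT10 lost its call without either control, copper 2, iron 1 or either double library (0.0730 to 0.182), and ZIP4, AT3G22600 and BCB without any control, iron or double library (0.0572 to 0.205). AT1G36622 lost it without any library but copper 1 and iron 1 (0.0597 to 0.149), and SUC2, AT2G25735 and AT4G13100 without any of the 8 (0.0588 to 0.240). CSD2 (1.06 ± 0.26, 0.192), CCS (0.91 ± 0.24, 0.212) and CSD1 (0.84 ± 0.18, 0.156) were not called over all genes and were over their list alone, where all 3 lay above the sum.

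**Figure D4:**
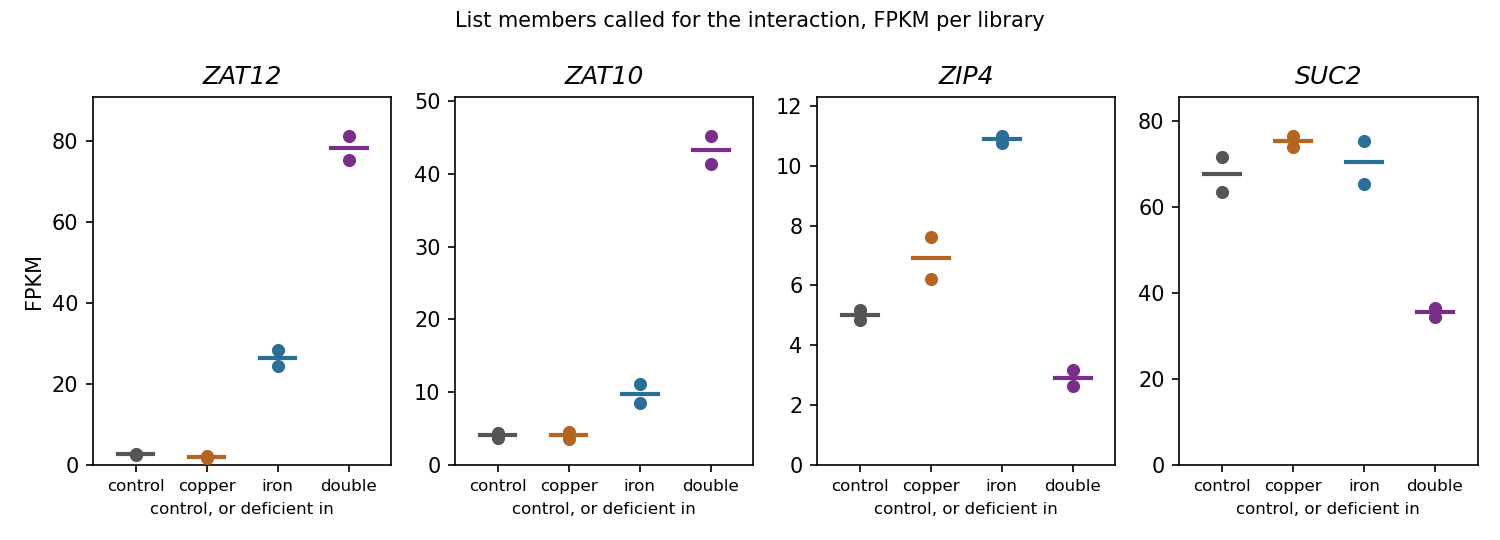
Messenger RNA of ZAT12, ZAT10, ZIP4 and SUC2 in the 4 groups. Dots are single libraries, bars are means (n = 2 per group), in FPKM on linear axes that start at 0. For each gene the value without both metals departed from the sum of the single changes on the log2 scale, upward for ZAT12 and ZAT10 and downward for ZIP4 and SUC2.

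For lists, the camera p-values compare members with the other genes, and not with a departure of 0 from the sum. By lists, members lay below the sum in several nutrient and tissue groups. Of the phloem markers all 3 did, and SUC2 was called (3 over the list alone; median -0.86 relative to an all-gene median of 0.14, adjusted p = 5.26e-05, and adjusted p = 0.232 with an estimated correlation). APL stood at -0.72 ± 0.16 (0.170) and AHA3 at -0.45 ± 0.14 (0.279). Of the zinc list 4 of 6 did and ZIP4 was called (1 rise and 2 falls over the list alone; median -1.15, adjusted p = 0.0141, and adjusted p = 0.434 with an estimated correlation). IRT3 stood at -1.05 ± 0.31 (0.248), ZIP5 at -0.98 ± 0.37 (0.336) and ZIP1 listed at 0 in 5 libraries. All 4 sulfur starvation genes lay below the sum with 0 called (median -0.92, adjusted p = 0.000871, and adjusted p = 0.394 with an estimated correlation). LSU1 stood at -1.08 ± 0.39 (0.322), SULTR4;2 at -0.82 ± 0.24 (0.248) and SDI1 at -0.75 ± 0.33 (0.385). All 5 guard cell markers did, 0 called and 2 over the list alone (median -0.60, adjusted p = 0.00183, and adjusted p = 0.434 with an estimated correlation). TGG2 stood at -0.84 ± 0.25 (0.248) and TGG1 at -0.83 ± 0.16 (0.135). The root-type iron uptake list did in 6 of 7 members (median -0.60, 0 called, adjusted p = 0.00422, and adjusted p = 0.349 with an estimated correlation), IRT1 at -0.73 ± 0.34 (0.407), FRO2 at -0.61 ± 0.24 (0.359) and COSY at -0.46 ± 0.23 (0.441). Photosystem II did in 20 of 22 members (median -0.37, 0 called, adjusted p = 5.88e-05, and adjusted p = 0.768 with an estimated correlation), LHCB4.3 at -0.92 ± 0.32 (0.312) and LHCB2.4 at -0.79 ± 0.23 (0.243). Chlorophyll synthesis did in 14 of 20 (median -0.22, 0 called, adjusted p = 0.00999, and adjusted p = 0.768 with an estimated correlation), PORA at -0.70 ± 0.31 (0.394) against HEMA1 at 0.60 ± 0.33 (0.477). The chlorophyll list lost its call without control 1, iron 2 or double 1 (adjusted p = 0.0943, 0.507 and 0.149) and the zinc list without copper 1 (0.0524) and under median-ratio or quantile scaling, and that of photosystem II was lost under quantile scaling. In the other direction lay all 16 salicylate genes (median 0.37, 0 called and 1 over the list alone, adjusted p = 0.0826, and adjusted p = 0.768 with an estimated correlation), PAD3 at 2.25 ± 0.46 (0.140) and PR1 at 2.03 ± 0.58 (0.242). The median of this list lay below that of all genes in each comparison with control, so high values in the shared controls could also place it above the sum. Of the reactive oxygen genes 12 of 14 lay above the sum and ZAT10 and ZAT12 were called (adjusted p = 0.0999), with OXI1 at 0.91 ± 0.26 (0.242) and APX1 at 0.63 ± 0.23 (0.322).

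The interaction test called 113 genes, 76 above and 37 below the sum (59 and 38 under median-ratio scaling), of which 79 had a group with both libraries listed at 0 and 34 lay above 0 in all libraries (31 above and 3 below the sum). By rank the former led. AT2G05765, ATCG00290, AT2G20722 (1295 and 575 FPKM) and MIR166e (770 and 676 FPKM) were listed above 0 in the 2 iron-deficient libraries and at 0 in the other 6, and U5.6 likewise in the 2 doubly deficient ones. MIR418, U4.8 and AT5G01145 were above 0 in the controls alone, AT4G39361 in the controls and in double deficiency (1510 and 336 FPKM), and AT1G55673 in all but the controls. Fewer genes were called at 5 FPKM in 2 libraries (58), without copper 2 and iron 1 (59), without control 2 (75), without iron 1 or 2 (61 and 74) and without double 1 or 2 (38 and 39). Double against iron deficiency, tested directly, gave 218 genes (180 up and 38 down; 99 and 66 under median-ratio scaling). It gave 844 among nuclear coding genes above 0 in all libraries, 515 with library weights, 373 with the robust spread, 354 with a pseudocount of 5 and 66 without copper 2 and iron 1. It gave 134 and 135 without control 1 or 2, 61 and 95 without iron 1 or 2, and 33 and 21 without double 1 or 2.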

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

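All tests of explanations in this part were chosen after the result was seen. For those of the most abundant transcripts and of handling, the bounds were written before the test itself was run. The touch and wound list for handling left out genes already seen. The patterns described below for copper deficiency and for iron deficiency, each against control, did not come from the interaction test. What brought the other results here is that test, of whether the change without both metals differs from the sum of the single changes. It called 113 genes.

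The first pattern is this set of 113 (58 at 5 FPKM in 2 libraries and 59 without copper 2 and iron 1), in which some genes lay far above the sum: BCB by 3.109, AT1G36622 by 2.606, AT2G25735 by 2.591, AT3G22600 by 2.534, AT3G21460 by 2.482, ZAT10 by 2.057 and ZAT12 by 1.825 on the log2 scale, with ZIP4 at -2.006, AT4G13100 at -1.133 and SUC2 at -1.123. Against values of 0 as the whole cause, a fit of nuclear coding genes above 0 in all libraries still called 139 genes, 131 above and 8 below the sum, though this leaves open the 79 called genes with a group at 0. In the fit of all tested genes 34 of these nuclear coding genes were called, fewer than the bound set for this test. How much of the set values of 0 explain thus depends on which genes were fitted. Handling around harvest stays open: of 16 touch and wound genes fixed before the test, 13 were tested, all 13 had a positive interaction with a median of 1.322 (0 called), at percentile 100 of 10000 random lists matched on expression (95th percentile 0.342). The random lists were not matched on correlation between genes, so the percentile does not allow for members of 1 response that vary together. TCH4 stood at 40.9 and 29.6 FPKM without both metals against 2.35 to 12.4 FPKM in the other 6 libraries, and TCH2 at 61.7 and 51.6 against 15.7 to 22.4 FPKM, and in double against iron deficiency 4 of the 13 were called (limma adjusted p = 0.0148 for TCH2, 0.0217 for ERF6, 0.0405 for ERF104 and 0.0410 for ERF5). Such genes also answer to oxidative stress, so that a response to the loss of both metals and a difference in handling of the 2 doubly deficient libraries may each underlie the pattern, and the design does not separate them.

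The second pattern is that each of the 35 genes called for copper deficiency had a group listed at 0. Failed estimates written as 0 may underlie them, since 159 nuclear coding genes stood at 10 FPKM or more in 1 library of a group and at 0 in its partner. Counting noise is argued against for called nuclear coding genes of at least 300 bp, whose higher group held a median of 66.03 implied fragments per library (lower quartile 27.43), or 3.69 per FPKM and kb of locus where all tested nuclear coding genes held 4.22. For the other called genes the bounds implied a median of 0.07705 fragments (0.00343 per FPKM and kb), too few for a listed gene, so that the scale does not hold for them and counting noise cannot be told apart from the rest there. A loss of transcripts through copper deficiency itself was not tested by other means.

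The third pattern is the excess of rises in iron deficiency, 5218 against 1314 falls. A changed share of organelle and ribosomal transcripts is argued against: with libraries scaled to nuclear coding genes, the median log2 change of these genes was 0.4982, above the 0.2675 before scaling. A fall of the most abundant nuclear transcripts may account for part of it. Scaling without the 200 highest in the controls brought the median to 0.1274. This lay between the bounds of 0.1 and 0.13, which were written before the test was run but after the excess was seen. Such a fall cannot be told apart there from a true rise of many genes, as FPKM give shares and not amounts.

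By camera on the interaction, these lists lay below the other genes: phloem markers (camera adjusted p = 5.2643e-05), photosystem II (5.8809e-05), sulfur starvation (0.00087126), guard cell markers (0.0018252), root-type iron uptake (0.0042159), chlorophyll synthesis (0.0099875) and zinc deficiency (0.01405), and with an estimated correlation none was called (lowest adjusted p = 0.232). Camera does not test a departure from the sum itself: the median of all genes lay 0.14 above it, and chlorophyll synthesis had a raw median of -0.09. Genes listed at 0 in a group were called for the interaction as well: AT2G05765 (limma adjusted p = 2.379e-06), U5.6 (1.342e-05), MIR166e (1.342e-05), MIR418 (2.494e-05), U4.8 (3.297e-05), AT5G01145 (3.658e-05), ATCG00290 (4.394e-05), AT1G55673 (4.394e-05), AT4G39361 (0.0005728) and AT2G20722 (0.0006222).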

How the results depend on the processing

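In this part the tests of genes above 0 in all libraries, of scaling to nuclear coding genes and of leaving out copper 2 with iron 1 were chosen after the data were seen. Of 7245 comparisons of 329 named results with an alternative, 6756 kept their direction and stayed called or not called, 339 lost a call, 80 gained one, 66 turned direction and 4 came to exactly 0. Of 216 called results 71 were lost under some alternative, and 1 turned. Where a value moved, the cause was not tested. A count-based tool could not be used, as counts were not used here, and the robust spread is not available in camera. The interaction needs all 8 libraries, so that fitting the compared groups alone was not possible for it. When a library was left out, the lone sample of its group was assumed to vary like the other groups. Replicate numbers are not shown to pair libraries: deviations from the group means correlated across groups at -0.0394 to 0.0238 over the tested genes. Over nuclear coding genes above 0 in all libraries they correlated at 0.0995 to 0.214, positive in all 6 pairs of groups. This is a hint from the data that replicate numbers share something, which the labels do not state and which 2 libraries per group leave open. Of the title letters, C stood for copper 2 alone, so the letter block leaves copper 1 as the only copper library that counts. For comparisons with the copper group it is therefore no check separate from leaving out copper 2. With replicate number as a block 208 of the 216 called results kept their call and 8 lost it, and of those not called 3 gained a call and 0 turned. With the title letter 196 kept and 20 lost it, 7 gained one and 7 turned.

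With 35 genes called for copper deficiency, a filter of 5 FPKM gave 23, scaling to nuclear coding genes 22, genes above 0 in all libraries 0, and leaving out 1 library 34 to 86 (56 without control 1). For iron deficiency 6532 genes became 10270 under scaling to nuclear coding genes and 3376 to 6826 with 1 library out (3463 without iron 2). For double deficiency 8654 became 5174 to 8951 (5650 without double 2, 5630 without control 2). For the interaction 113 became 58 at 5 FPKM, 68 with the replicate block, 44 with the letter block, and 59 without copper 2 and iron 1. It became 38 to 131 with 1 library out (75 without control 2, 61 and 74 without iron 1 and 2, 39 without double 2). For double against copper deficiency 8779 became 5235 to 8392 (5715 without double 2). For double against iron deficiency 218 became 354 with a pseudocount of 5, 373 with the robust spread, 515 with library weights, 133 with the replicate block, 51 with the letter block, 844 among genes above 0 in all libraries, and 66 without copper 2 and iron 1. It became 21 to 221 with 1 library out (134 and 135 without control 1 and 2, 61 and 95 without iron 1 and 2, 33 without double 1). For iron against copper deficiency 6703 became 3380 with the letter block, 10340 under scaling to nuclear coding genes, 3638 without copper 2 and iron 1, and 3612 to 6195 with 1 library out.

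With an estimated correlation 0 lists were called in each comparison, against 4 for copper, 10 for iron, 9 for double deficiency and 7 for the interaction. That form of the test rests on 4 residual degrees of freedom. It did not call the leaf iron response in iron deficiency (camera adjusted p = 0.350), where limma called all 15 tested members. Its lack of calls therefore says little for or against a list. Copper lists came to 7 with the letter block and without copper 2 and iron 1, and to 3 to 7 with 1 library out. Iron lists came to 9 to 11 and double deficiency lists to 9 to 10 with 1 library out. Interaction lists came to 11 under scaling to nuclear coding genes, 12 without copper 2 and iron 1, and 6 to 11 with 1 library out. The correlation of copper and iron changes, 0.289, became 0.1147 among genes above 0 in all libraries, 0.1727 under scaling to nuclear coding genes and 0.2056 to 0.4566 with 1 library out.

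Direction turned for the flavonoid list in iron deficiency (adjusted p = 0.9072 without control 2, 0.4221 without iron 1, 0.9312 under scaling to nuclear coding genes and 0.4728 without copper 2 and iron 1), the root-type iron uptake list in double deficiency (0.7935 at 5 FPKM) and the jasmonate list there (0.8658 under quantile scaling). The 1 called gene that turned was CSD1 in double deficiency, at -0.03494 under median-ratio scaling. The other turns, in log2 changes of genes not called, follow by setting.

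In copper deficiency these were, without control 1, FER1 (0.1111), and without copper 1, BHLH39 (-0.05607), IMA1 (0.4063) and OPT3 (0.2252). Without copper 2, and likewise without copper 2 and iron 1, they were KAT1 (-0.01248), BHLH100 (-0.2296), FRO3 (-0.3772) and FER1 (0.03186), and with the letter block BHLH100 (-0.3784), FRO3 (-0.3743) and FER1 (0.1134). In iron deficiency they were BTSL2 under quantile scaling (-0.00185), CSD1 (-0.1556) and CSD2 (-0.2706) under median-ratio scaling, CSD2 without control 1 (-0.2219) and iron 2 (-0.08755), and CCH under scaling to nuclear coding genes (0.08194). In double deficiency they were F6'H1 without control 2 (0.6229) and double 1 (0.2896), SULTR4;2 without control 1 (0.04163) and double 2 (0.1541) and under scaling to nuclear coding genes (0.05135), AHA3 under median-ratio (-0.3677) and quantile scaling (-0.2910), and CSD2 under median-ratio (-0.4282) and quantile scaling (-0.008251) and without control 1 (-0.2254). The 4 changes that came to exactly 0 were those of EDS5 and BHLH38 in copper deficiency without control 2, and of CDKB1;1 in iron deficiency without iron 2 and in double deficiency without double 2.

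In the interaction COPT2 turned under median-ratio (-0.08838) and quantile scaling (-0.07192), without control 1 (-0.2706), copper 1 (-0.05351), iron 1 (-0.2309) and double 2 (-0.06652), under scaling to nuclear coding genes (-0.05568) and without copper 2 and iron 1 (-0.1110). BHLH39 turned with a pseudocount of 0.1 (-0.1095), under median-ratio (-0.1080) and quantile scaling (-0.2275), with the letter block (-0.05045), without copper 2 (-0.07552) and iron 1 (-0.004091), under scaling to nuclear coding genes (-0.1008) and without copper 2 and iron 1 (-0.1337). With the letter block, without copper 2, and without copper 2 and iron 1, BHLH100 (0.2205, 0.07167 and 0.06404), FRO3 (0.3727, 0.3757 and 0.3489) and OPT3 (0.05177, 0.08802 and 0.06247) turned. KAT1 turned without copper 2 (0.0005008) and without copper 2 and iron 1 (0.03111), and IMA1 without copper 1 (-0.2310).

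With 1 library left out, the results that turned or came to 0 had these lowest and highest values. In iron deficiency the adjusted p of the flavonoid list ran from 0.09613 to 0.9072, CDKB1;1 from 0 to 2.615 and CSD2 from -0.2219 to 0.2876. In copper deficiency EDS5 ran from -2.704 to 0, KAT1 from -0.01248 to 0.2767, BHLH38 from -0.9367 to 0 and BHLH39 from -0.05607 to 0.2031. BHLH100 ran from -0.2296 to 1.074, IMA1 from -1.779 to 0.4063, FRO3 from -0.3772 to 0.6595 and OPT3 from -0.5168 to 0.2252. FER1 ran from -0.5192 to 0.1111. In double deficiency F6'H1 ran from -1.289 to 0.6229, CDKB1;1 from 0 to 2.88, SULTR4;2 from -0.2308 to 0.1541 and CSD2 from -0.2254 to 0.2841. For the interaction KAT1 ran from -0.2887 to 0.0005008, COPT2 from -0.2706 to 0.4035, BHLH39 from -0.07552 to 0.1837 and BHLH100 from -1.232 to 0.07167. IMA1 ran from -0.231 to 1.955, FRO3 from -0.661 to 0.3757 and OPT3 from -0.6541 to 0.08802.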

Other observations

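Some flowering and cell division genes rose in leaves without iron, although neither list was called. Of 10 flowering genes 5 rose in iron deficiency and 7 in double deficiency (4 and 6 under median-ratio scaling; adjusted p = 0.241 and 0.0664). The floral regulator FUL stood at 0.733 ± 0.405 FPKM in controls, 4.19 ± 0.365 without iron (log2 1.60 ± 0.22, adjusted p = 0.00353) and 5.18 ± 0.216 without both (1.85 ± 0.22, 0.00137). SEP3 stood at 0.439 ± 0.0726, 2.80 ± 1.48 (1.34 ± 0.31, 0.0183) and 3.83 ± 0.301 FPKM (1.75 ± 0.31, 0.00542). SEP1 was listed at 0 in all control and copper-deficient libraries, at 1.39 and 1.69 FPKM without iron and 2.98 and 2.48 without both. SEP2 stood at 0 and 0.00899 FPKM in controls, 1.29 and 1.61 without iron and 3.04 and 2.27 without both. The mitotic cyclin CYCB1;1 rose from 1.08 ± 0.481 to 20.6 ± 1.35 (3.39 ± 0.19, 0.000149) and 26.7 ± 3.26 FPKM (3.75 ± 0.19, 8.30e-05). The kinase CDKB2;1 rose from 6.05 ± 0.807 to 18.9 ± 1.35 (1.498 ± 0.19, 0.00277) and 20.9 ± 0.0913 FPKM (1.64 ± 0.19, 0.00128). Of the 4 division markers 3 rose in each (2 under median-ratio scaling; adjusted p = 0.103 and 0.146), the third KNOLLE, listed at 0 in the controls, with 10.1 and 8.43 FPKM without iron, and CDKB1;1 was listed at 0 in 5 libraries. SEP3 lost its call in iron deficiency without control 1, control 2 or iron 2 (0.0558, 0.0797 and 0.0694) and KNOLLE without any control, iron or double library, both in iron (0.0754 to 0.151) and in double deficiency (0.0542 to 0.111). Among annotation terms, a search added after the data were seen, microtubule-based movement was overrepresented in rises, 15 of 40 genes in iron deficiency (1.77 by chance; Fisher's exact test, adjusted p = 9.23e-09) and 11 of 40 in double deficiency (2.29; 0.000807), where the nucleolus was too (31 of 191, 11.0 by chance; 2.04e-05). Nucleosome assembly was overrepresented in falls without iron (9 of 50, 2.18 by chance; exact test, 0.00284), as were photosynthesis (39 of 66, 2.88; 2.84e-34) and the apoplast (30 of 166, 7.24; 9.75e-10). Genes above the sum in the interaction, a set of 32, held 4 of 97 genes of the response to oxidative stress (0.259 by chance; exact test, 0.0192). That term was also overrepresented among falls, with 17 of 97 genes in iron deficiency (4.23 by chance; exact test, 1.52e-05). In double deficiency 17 of 97 fell as well (4.97 by chance; exact test, 0.000120), so the term points in no single direction.

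Senescence genes divided: without iron 4 rose and 3 fell of 11 (adjusted p = 0.103). The sugar transporter SAG29 rose from 1.88 ± 0.201 to 66.9 ± 9.51 FPKM (4.55 ± 0.52, 0.00209), while the chlorophyll b reductase NYC1 fell by 3.63 (± 0.13, 2.38e-05), SEN1 by 1.97 (± 0.14, 0.000379) and NAP by 1.37 (± 0.23, 0.00702) on the log2 scale. Without both, 3 rose and 4 fell, 5 and 4 over the list alone (0.0999), with a median of 0.60 and a mean of 0.17 where the test pointed down. Of 13 flavonoid genes 4 rose in each (0.707 and 0.524), among them the regulator PAP1, from 25.02 ± 5.92 to 68.7 ± 14.3 without iron (1.42 ± 0.22, 0.00490), and TT8 (1.03 ± 0.23, 0.0171), with UF3GT at 0.95 ± 0.51 (0.199) and TT19 listed at 0 in the controls and at 69.4 and 45.9 FPKM without iron. TT8 lost its call without control 2 or iron 1 (0.0822 and 0.0674) and TT19 without either control or iron library (0.0869 to 0.104). Of 14 jasmonate genes 1 rose and 2 fell without iron (0.103) and 5 rose and 3 fell without both (0.345; 1 and 3 under median-ratio scaling), with JAZ5 (1.34 ± 0.35, 0.0228), MYC2 (1.32 ± 0.30, 0.0141), JAZ7, at 3.05 and 2.76 FPKM, and PDF1.2 at -2.07 ± 0.81 (0.0791). JAZ5, JAZ7 and MYC2 lost their calls under median-ratio scaling and without some control and double libraries: JAZ5 without control 2, double 1 or 2 (0.101, 0.108 and 0.0586), JAZ7 without control 1, double 1 or 2 (0.0735, 0.0885 and 0.0687), and MYC2 without control 2 or double 1 (0.0721 and 0.0690). Of 4 sulfur genes 2 rose without iron, with 1 fall over the list alone (0.855), and without both LSU1 (-2.47 ± 0.28, 0.00117) and SDI1 (-1.1025 ± 0.23, 0.0103) fell and LSU2 rose by 0.76 (± 0.09, 0.00118), with SULTR4;2 at -0.04 ± 0.17 (0.873; list 0.0665). SDI1 lost its call without control 1 or double 1 (0.0503 and 0.0551).

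Of the remaining lists, zinc genes rose in 3 of 6 without iron, 4 over the list alone (adjusted p = 0.2501), and rose in 2 and fell in 2 without both (0.218). Phosphate genes rose in 2 and fell in 1 of 7 in each (0.996 and 0.490), and heat shock genes rose in 4 of 5 and 2 of 5 (0.324 and 0.585). Guard cell markers rose in 2 and fell in 1 of 5 without iron (0.452), the median of -0.13 turning to 0.17 under quantile scaling, and rose in 2 and fell in 3 without both (0.0664). Phloem markers rose in 2 of 3 without iron (0.2501). Without both, APL rose by 0.65 (± 0.11, 0.00517), not under median-ratio or quantile scaling, SUC2 fell by 0.91 (± 0.11, 0.00133) and AHA3 stood at 0.08 ± 0.10 (0.546; list 0.318). Xylem genes were called in 0 of 3 (0.996 and 0.388), and of the clock genes 7 of 12 rose without both, 8 over the list alone (adjusted p = 0.126; 4 rose and 2 fell under median-ratio scaling). The root gene PYK10, the 1 tested of its list, stood at 0.62 without iron, 0.97 without both and -1.13 without copper on the log2 scale, and was not called.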
